A study of Bos taurus with 4 samples.

How the data were processed

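RNA from 4 pools of 200 immature bovine oocytes was depleted of ribosomal RNA and parted on poly(A)-binding beads, per the labels' protocols. RNA in the flow-through and washes was taken as A-, and RNA eluted at 75 °C, after an elution at 42 °C that is not analysed here, was taken as A150. Both fractions were amplified with WT-Ovation One-Direct and labelled by the Universal Linkage System, per the labels' protocols. Amplification from small amounts and priming can favour some transcripts, and the amount of RNA per fraction was not recorded in the sources used here, so a ratio compares relative signals. The labels name A150 and A- in the 2 dyes of each array, which sets the direction of every ratio. The pools are separate per the series design text, and the p-values of probes and genes measure the spread between pools and arrays together.

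The deposited files of each array hold spot intensity values, per the file headers: the mean and median brightness of each spot and the local background in the green (Cy3) and red (Cy5) scans, without subtraction. The scanner and image software are not given in the sources used here. Rows without a probe name (22 per file) were left out. The deposited table of the whole series holds log2 ratios made by the authors. Its columns correlated at 0.996 to 0.999 with loess-normalized log2 ratios of A150 over A- computed without background correction, with slopes of 1.03, 1.22, 1.09 and 0.84 and medians of -0.011, -0.010, 0.020 and 0.012. All 4 columns therefore run as A150 over A-, on a log2 scale and centred near 0, and the reason for the differing slopes stays unknown.

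Spot means were background corrected with normexp and an offset of 50 and normalized within each array by loess with control spots at weight 0, with no normalization between arrays, in limma 3.58.1 under R 4.3.3. The signs of arrays 3 and 4 were turned. A spot counted as above background when its mean exceeded the mean plus 2 SD of 153 negative-control spots in that channel. The local background lay far below the negative-control spots: on array 1 the Cy3 channel had a median local background of 40 against a negative-control mean of 1078. A probe was kept when it was above background in at least 1 fraction on at least 3 arrays. Saturated spots were kept. A probe not above background in 1 fraction on any array has only a bound, computed from single channels after loess and Aquantile. The bound comes from means over arrays and leaves out the spread between arrays and between processing settings. Single arrays and other settings can therefore lie below it. The number of arrays limits the precision of every value.

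Gene symbols came from the platform annotation. Of 43794 bovine probes, 21790 had 1 symbol, 0 had several and 22004 had none; 20025 symbols were current in the RefSeq table of the assembly ARS-UCD2.0, 1524 were updated through a unique synonym and 241 were kept as annotated. No genomic coordinates are given because the array's build is not given in the sources used here. A gene was represented by its kept probe with the highest mean signal; 1622 genes had more than 1 kept probe. The log2 ratios of the 2 brightest probes of a gene correlated at r = 0.41 across these genes, and 13 genes had probes that passed an unadjusted p under 0.05 with the same sign on all arrays on opposite sides.

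The log2 ratios were tested against 0 with limma (lmFit and eBayes, 3 residual degrees of freedom, Benjamini-Hochberg adjustment, threshold 0.05). The 2 fractions of a pool share an array, so the pairing is part of the ratio. The 22 gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, for lists with at least 5 measured genes. Camera at the preset correlation sets a list's genes against the other genes, so its p-values do not measure the spread between pools. List medians were taken on each array and are given as mean ± SD of the 4 arrays. The alternatives and the random lists of matched signal used another summary, the median over genes of each gene's mean ratio, and the 2 differ in size; it is called the median of gene means. Named genes followed a rule written before the data were examined: on each side, up to 12 genes past the threshold with the same sign on all arrays, filled with the smallest p where fewer passed, without locus numbers or clone names; the 2 members of each list with the smallest p on each side; all measured replication-dependent histones; and GDF9, BMP15, CCNB1, MOS, PLAT, ZP3, ACTB and GAPDH. Single microRNA loci that the rule takes are not named. ATF2, MYL6 and other genes in the closing observations, and the unnamed probe in the report, were chosen after their values were seen.

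The fit was checked on simulated data with spreads drawn from the prior that limma fitted to the probes. The noise was independent between probes, so errors shared by the probes of an array were not simulated. Among 19453 simulated probes, 0 of 100 changed by 2 on the log2 scale and 53 of 100 changed by 4 were recovered, with 0 false calls. Among 2030 simulated probes, with the prior fitted to those above background in both fractions, 51 and 98 of 100 were recovered with 5 false calls.

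Alternatives tried were no background correction, normexp with offset 0, local background subtraction, median centring, no normalization within arrays, Aquantile between arrays, no filter on dim probes, a strict filter (above background in both fractions on all 4 arrays), a dye covariate, single channels without the pairing, array weights, the authors' log2 table, each array left out, the mean of a gene's probes, other thresholds and an unmoderated one-sample test. Normexp against the negative-control spots and a threshold of 0.10 were added after the data were seen. A slide block and transcript features (length, sequence motifs) were not analysed here.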

Results

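Fully grown bovine oocytes store maternal mRNAs, and the length of an mRNA's poly(A) tail is tied in oocytes to whether the message is stored or translated. The series compared 2 tail-length fractions of RNA from immature Holstein oocytes at the germinal vesicle stage, that is, before meiosis resumes. The fraction called A150 holds RNAs that the labels describe as having tails of at least 150 nucleotides. The fraction called A- holds RNAs that the beads did not retain, described as having tails of at most 50 nucleotides. There were 4 pools of 200 oocytes, and the A150 and A- fractions of each pool were hybridised together on 1 two-colour array. A150 was in Cy5 on arrays 1 and 2 and in Cy3 on arrays 3 and 4. All ratios below are log2 signal of A150 over A-, so a positive value is a higher relative signal in A150, given as mean ± SD of the 4 arrays. Each array was centred during normalization, so a ratio is relative to the typical probe of that array and not to an absolute amount of RNA.

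Of 43794 bovine probes, 40.9%, 10%, 42.6% and 60.6% were above the negative-control spots in A150 on arrays 1 to 4, and 48.7%, 30.5%, 22% and 34.3% in A-. Array 2 had the fewest A150 probes above that level. In that channel the negative-control spots had a mean of 1570 and an SD of 449, the largest SD of any channel. The level there was 2467, against a median signal of 1574, so the low share need not mean fewer A150 transcripts. With 4362 probes above the level, that channel also limits the set above background on all arrays. A total of 19453 probes were kept, of which 10032 carried a gene symbol, and 7795 genes were tested. Across the kept probes, the log2 ratios of 2 arrays correlated at r = 0.29 to 0.32 in the same dye orientation and at r = 0.12 to 0.29 between orientations. Among the 2030 probes above background in both fractions on all 4 arrays, these ranges were 0.44 to 0.49 and 0.32 to 0.54. These correlations are across probes, which are not independent replicates. The ratio had the same sign on all 4 arrays for 22.1% of kept probes, against 12.5% with no relation between arrays.

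The first comparison asked which transcripts were relatively higher in A150 or in A- in immature oocytes. SATB1, which encodes a chromatin organiser, had the lowest ratio among named probes that passed, at -4.43 ± 0.39 (SD, n = 4), or 21.5-fold higher in A- (limma adjusted p = 0.0482). H2AJ, a histone H2A variant, was 17.4-fold higher in A- (-4.12 ± 0.42, SD, n = 4, limma adjusted p = 0.0482). A probe of EEF1A1, which encodes a translation elongation factor, was 11.5-fold higher in A- (-3.52 ± 0.30, SD, n = 4, limma adjusted p = 0.0482). That probe was above background in A150 on 2 arrays only. A second, brighter probe of EEF1A1 had a ratio on the opposite side, at 1.74 ± 0.97, so the gene has no single direction here. The other 9 probes higher in A- had no gene symbol, and the probe EMBV3_31936 had the lowest ratio, at -6.07 ± 0.73. It was above background in A150 on 2 arrays only, so its size is uncertain. In all, limma called 12 probes higher in A- and 0 higher in A150 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1061 and 1563 probes, and an unmoderated one-sample test called 0 in either direction after adjustment. Only 4 of the 12 called probes were above background in both fractions on all 4 arrays, so the sizes of the others are uncertain. The 12 calls lay close to the threshold, with adjusted p from 0.0482 to 0.0486. Their number was 0 with any 1 array left out, and the counts without normalization within arrays were 300 higher in A150 and 355 higher in A-. Restricting the test to the 2030 probes above background in both fractions gave 116 probes higher in A150 and 128 higher in A-, and limma on the 8 single channels, without the pairing by array, called 199 probes, 76 of them higher in A150 and the others higher in A-.

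With 1 probe per gene, limma called 0 genes in either direction at an adjusted p under 0.05, with 758 genes toward A150 and 327 toward A- at an unadjusted p under 0.05. The smallest adjusted p was 0.0889 toward A150 and 0.0801 toward A-. Without normalization within arrays the counts were 89 and 49 genes. On the single channels without the pairing, they were 15 and 12. Among genes above background in both fractions on all 4 arrays, only 1 gene was called, higher in A-. The genes named next are therefore those with the smallest p on each side and the same sign on all 4 arrays, and none of them passed at the level of genes.

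On the A150 side, the 12 genes had ratios from 2.26 to 3.70. SLC35B1, a solute carrier gene, had the highest mean (3.70 ± 0.74). However, its probe was above background in A- on 1 array only and a second probe stood at 2.24, so its size and rank are uncertain. COA8, needed for cytochrome c oxidase assembly, stood at 3.19 ± 0.49, and PEBP1, an inhibitor of the RAF kinase, at 3.06 ± 0.35. CCNB2, which encodes the M-phase cyclin B2, stood at 2.76 ± 0.30 and had values from 2.45 to 3.16 on the 4 arrays. COX7C and NDUFA8, subunits of the respiratory chain, stood at 2.97 ± 0.51 (above background in A- on 1 array) and 2.81 ± 0.53. RPS13, a protein of the small ribosomal subunit, had the smallest spread of these genes (2.26 ± 0.12). The others were WDR3 (3.03 ± 0.62), GYG1 (2.92 ± 0.39), HIST1H2BN (2.44 ± 0.29) and TRAPPC1 (2.36 ± 0.20). SH3GLB2 was not well above background in A- on any array by the probe used. The bound from its means, 6.46-fold, was close to the 6.65-fold of its mean ratio. For this gene 2 further probes had smaller ratios (0.91 and 0.16).

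On the A- side, the 12 genes had ratios from -4.43 to -2.21. After SATB1, the lowest ratios were those of HACD4, a fatty acid elongation gene (-4.19 ± 0.89, above background in A150 on 1 array), H2AJ, and CBFB, the partner of RUNX transcription factors (-3.69 ± 0.82). SAR1B, a GTPase of vesicle export from the endoplasmic reticulum, stood at -3.07 ± 0.39. EIF4E, the mRNA cap-binding protein of translation initiation, stood at -2.53 ± 0.47. HSPA2, an HSP70 family member, stood at -2.39 ± 0.38 (adjusted p = 0.0889), CEP290 at -2.42 ± 0.44 and TSEN15, a tRNA splicing gene, at -2.45 ± 0.35. SLC6A2, TRARG1 and BRPF3 stood at -2.84 ± 0.64, -2.43 ± 0.47 and -2.21 ± 0.33. Further probes had ratios of -0.15 and -0.62 for HACD4 and of -0.37 and -0.48 for TSEN15, so the low ratio of each rests on 1 of 3 probes.

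**Figure D1:**
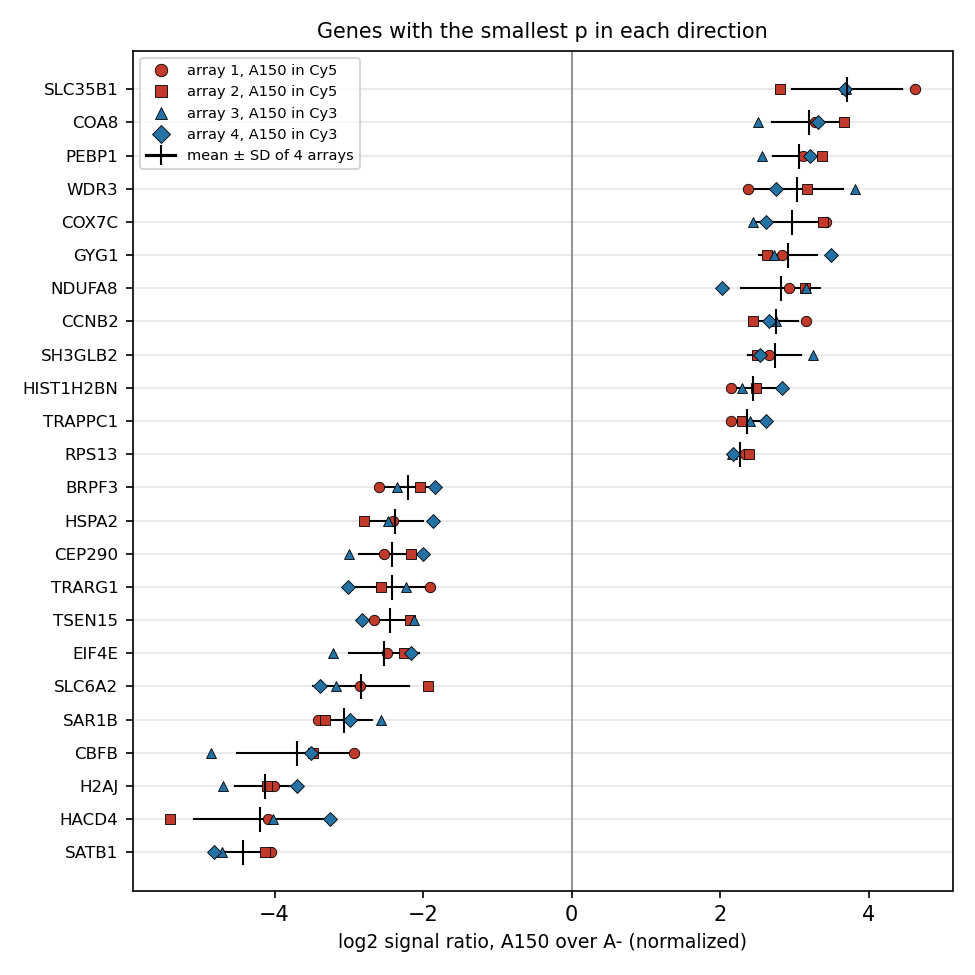
Log2 signal ratio of A150 over A- (horizontal axis) of the 12 genes with the smallest p on each side; each symbol is 1 array, red with A150 in Cy5 and blue with A150 in Cy3, and the black mark and line are the mean and SD of 4 arrays. All 4 arrays lie on the same side of 0 for each gene because only such genes were chosen. Means run from 2.26 to 3.70 on the A150 side and from -4.43 to -2.21 on the A- side, and no gene passed an adjusted p of 0.05.

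Gene lists fixed before the data were examined were then compared with all other genes. Of 22 lists, 21 had at least 5 measured genes, and camera with a preset correlation placed 10 higher in A150 and 1 higher in A-. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.127. The estimate lay above the preset 0.01 for some lists, such as cytosolic ribosomal proteins (0.099). It lay below 0.01 for others, such as mitochondrial ribosomal proteins (-0.012) and proteasome subunits (-0.012), so a higher correlation does not account for their lost calls. The test fry, which asks whether a list's genes lie on balance on 1 side, passed 8. With 4 arrays, an exact two-sided sign-flip permutation test of a list's median cannot give a p below 0.125.

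Among the kept probes, messages of the cytosolic ribosome had the largest group shift toward A150. Of 61 measured ribosomal protein genes, 58 had a positive ratio, and the list's median averaged 1.34 ± 0.52 over the 4 arrays, or 2.53-fold. Camera gave an adjusted p of 3.64e-15 (adjusted p = 0.127 with an estimated correlation, which was 0.099). In this list 26 genes passed toward A150 and 0 toward A- when adjusted over the list alone, and 0 over all genes tested. RPL38 stood at 2.67 ± 0.86 (above background in A- on 1 array) beside RPS13. RPS9 (-0.44 ± 0.98) and RPS3A (-0.78 ± 2.05) had negative means with wide spreads and no settled direction. A second probe of RPS9 stood at 0.48 and the mean of its probes at 0.02. RPS3A ranged from -1.64 to 0.00 with 1 array left out. Nuclear-encoded genes of oxidative phosphorylation had a positive ratio in 62 of 69 genes and a median of 1.12 ± 0.57, or 2.17-fold. Camera gave an adjusted p of 2.03e-11 (adjusted p = 0.127 with an estimated correlation, which was 0.091). In this list 15 genes passed toward A150 adjusted over the list alone, with 0 over all genes tested. CYC1 (-0.71 ± 0.81) and NDUFB3 (-0.48 ± 1.85) had negative means, but a second probe of CYC1 stood at 0.49 and NDUFB3 was 0.37 without array 3. Among genes above background in both fractions on all arrays the order differed: the median of gene means was 1.01 (1.36 among all kept genes) for cytosolic ribosomal proteins, 1.03 (0.68) for splicing genes, 1.32 (0.90) for oxidative phosphorylation and 1.40 (0.60) for mitochondrial ribosomal proteins, and the splicing and mitochondrial ribosomal lists did not pass there. With all kept genes, mitochondrial ribosomal proteins were higher in A150 as a list (median 0.51 ± 0.12, camera adjusted p = 0.0117, adjusted p = 0.127 with an estimated correlation), with 36 of 54 genes positive and 0 passing adjusted over the list alone. In it MRPS15 stood at 1.22 ± 0.19 and MRPL20 at 1.81 ± 0.79, while MRPS10 stood at -1.88 ± 0.90 and MRPL22 at -1.69 ± 2.06. Without array 2 that list's adjusted p was 0.0565.

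Heat shock, stress and immediate early genes were higher in A150 as a list, with a median of 0.98 ± 0.36 (camera adjusted p = 0.000568, adjusted p = 0.127 with an estimated correlation). A positive ratio was found in 21 of 28 genes, and 6 passed toward A150 adjusted over the list alone. HSPE1, a mitochondrial co-chaperone, stood at 1.86 ± 0.69 and SOD2, the mitochondrial superoxide dismutase, at 2.02 ± 0.85, whereas TXN stood at -0.37 ± 0.18 and GADD45A at -0.60 ± 0.68. TXN was positive (0.30) with median centring.

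Oocyte-specific and maternal-effect genes were higher in A150 as a list (median 0.81 ± 0.27, camera adjusted p = 0.00531, adjusted p = 0.127 with an estimated correlation). Of 35 genes 25 were positive, and adjusted over the list alone 12 passed toward A150 and 1, BTG4, toward A-. The oocyte linker histone H1-8 stood at 2.17 ± 0.77, the oocyte transcription factor FIGLA at 1.79 ± 0.36, the growth factor GDF9 at 1.70 ± 1.07 and the zona pellucida gene ZP3 at 1.70 ± 1.01. BTG4, an adaptor of the CCR4-NOT deadenylase, stood at -1.38 ± 0.46 and the meiotic kinase gene WEE2 at -1.24 ± 0.81. BMP15, the partner growth factor of GDF9, had a normalized ratio near 0 (-0.02 ± 0.24). That ratio was positive with median centring (0.55), without normalization within arrays (0.21) and without array 3 (0.08). The list's adjusted p was 0.921 among genes above background in both fractions, and its median of gene means, 0.62, lay at the 95.8 percentile of random lists of matched signal. That value was 1.04 without array 4.

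Cell cycle and meiotic maturation genes were higher in A150 as a list (median 0.45 ± 0.34, camera adjusted p = 0.0322, adjusted p = 0.254 with an estimated correlation), and 39 of 55 were positive. Adjusted over the list alone, 6 passed toward A150 and 3 toward A-. CCNB2 and SYCP3, a protein of the synaptonemal complex (1.80 ± 0.29), were on the A150 side. CDC27 (-2.74 ± 0.74) and ANAPC10 (-2.88 ± 1.35), subunits of the anaphase-promoting complex, were on the A- side by the probes used, and a second probe of CDC27 stood at -0.50 ± 2.53. The list's adjusted p was 0.265 without array 1 and 0.215 without array 2. MOS, the kinase that holds eggs in meiotic arrest, stood at 1.67 ± 0.77, with 2 of its 4 probes near or below 0. CCNB1, which encodes cyclin B1, stood at 0.13 ± 1.52, and at -0.63 without array 2.

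Messages whose tails are known to lengthen in maturing vertebrate oocytes did not shift as a group in these immature oocytes (median 0.07 ± 0.32, camera adjusted p = 0.906). The list drew on mouse, cattle and Xenopus oocytes as background, and the direction by species is not settled. Its median of gene means, -0.06, ranged from -0.23 to 0.26 with 1 array left out. Of 29 genes 14 were positive and 15 negative, and adjusted over the list alone 3 passed toward A150 and 1 toward A-. CCNB2 and AURKA, a mitotic kinase gene (1.60 ± 0.60), stood on the A150 side and BTG4 and CDK2 (-1.90 ± 1.28) on the A- side. The list of poly(A) tail and mRNA storage machinery did not shift either (median -0.06 ± 0.11, camera adjusted p = 0.528). Among its 53 genes CPSF3 stood at 1.58 ± 0.55, PAIP1 at 1.24 ± 0.39 and EIF4E at the other end.

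The other lists higher in A150 were splicing and snRNP genes (median 0.47 ± 0.27, 39 of 56 positive, camera adjusted p = 0.0178), cytoskeleton and housekeeping genes (0.81 ± 0.14, 16 of 22 positive, 0.0178), proteasome subunits (0.62 ± 0.22, 21 of 33 positive, 0.0231) and translation initiation and elongation factors (0.42 ± 0.19, 32 of 50 positive, 0.0334). For each of these the adjusted p was 0.127 with an estimated correlation, and the cytoskeleton list's median of gene means, 0.67, lay at the 91.1 percentile of random lists of matched signal. Adjusted over the list alone, 0, 7, 1 and 6 genes passed toward A150, and 1 gene, EIF4E, toward A-. Splicing genes included SNRPG (2.12 ± 0.84) and HNRNPDL (1.67 ± 0.31) against PRPF18 (-2.03 ± 1.03) and SNRNP40 (-2.21 ± 1.23), but further probes stood at -0.26 and 0.93 for HNRNPDL and at -0.97 and 0.77 for PRPF18. Among cytoskeleton and housekeeping genes TMSB10, an actin-binding thymosin, stood at 3.24 ± 1.45 and TUBA1A at 1.44 ± 0.31, while ACTB stood at -0.99 ± 0.91, TBP at -1.21 ± 0.80 and YWHAZ at -2.02 ± 1.61. Proteasome genes included PSMB7 (2.29 ± 0.75) and PSMA6 (2.09 ± 0.94) against PSMD11 (-2.32 ± 1.92) and PSMA3 (-1.30 ± 1.69). Translation factors included EIF4G2 (2.29 ± 0.54) and EIF3K (2.23 ± 0.50) against EIF4E and EIF5 (-1.60 ± 1.07). Without array 2 the adjusted p was 0.0891 for cytoskeleton genes, 0.134 for proteasome subunits and 0.0537 for translation factors. Without array 1 it was 0.0619 for splicing genes, and translation factors had 0.0996 without array 3 and 0.0548 without array 4.

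Zinc finger transcription factors were the 1 list higher in A- (median -0.08 ± 0.11, camera adjusted p = 0.0363, adjusted p = 0.127 with an estimated correlation). A negative ratio was found in 96 of 155 genes, and 0 passed adjusted over the list alone. ZNF664 (-1.91 ± 0.68) and ZNF24 (-2.49 ± 1.29) stood on the A- side and ZPR1 (1.46 ± 0.27) and ZNF419 on the A150 side. ZNF419 was not well above background in A- on any array. The bound from its means, 3.25-fold, was the same as the fold of its mean ratio and is no lower limit. The log2 ratio of ZNF419 was 1.28 to 2.48 on single arrays and ranged from 0.95 to 2.98 over the alternatives. ZPR1 entered the list by its older symbol, ZNF259, and whether each member is a transcription factor was not checked. The list's adjusted p was 0.135 without array 1 and 0.123 without array 4, and its median was positive (0.08) on array 3.

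Replication-dependent histone messages, most of which end in a stem-loop and carry no poly(A) tail, were examined as messages without tails. They did not pass as a list (6 genes, median -0.38 ± 0.44, camera adjusted p = 0.300), and their single values went both ways. Their median of gene means, -0.63, lay at the 1.9 percentile of random lists of matched signal, toward A-, and was -0.22 without array 1. H1-2 stood at -4.17 ± 1.56 and H2AC20 at -2.39 ± 0.68, and both passed adjusted over the list alone, as did HIST1H2BN on the opposite side (2.44 ± 0.29). H2BC21 (-0.82 ± 2.02), H1-12 (0.44 ± 0.42) and H2BC5 (-0.44 ± 0.49) did not pass. H2BC5 was not well above background in A150 on any array, and its ratio was 0.05 on array 1, so no bound is given. H2BC21 was 0.17 without array 1, and H1-12 was -0.09 without normalization within arrays, where the median of all genes was -0.38. Several of these symbols were updated from older names through synonyms (HIST1H1E became H1-12), and what the histone probes target was not checked, so the split among single histones is uncertain. The 5 polyadenylated histone variants were also split (median -0.03 ± 0.55, camera adjusted p = 0.536; median of gene means -0.23, and 0.32 without array 4), with H1-8 on the A150 side, H2AJ on the A- side, and H3F3C (0.59 ± 1.04) and H2AZ2 (-0.71 ± 1.01) between them.

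Markers of cells that can adhere to oocytes showed no group shift. Of 13 cumulus and granulosa cell markers (median -0.12 ± 0.17, camera adjusted p = 0.906) 1, SERPINE2, a protease inhibitor gene, passed toward A150 adjusted over the list alone (2.01 ± 0.31). STAR stood at 0.40 ± 1.07 (further probes at -0.06 and 1.83), CD44 at -0.21 ± 0.34 and INHBA at -0.23 ± 0.91 (0.04 without array 2). The 9 stroma, endothelium and blood markers had a median of 0.01 ± 0.11 (camera adjusted p = 0.990), with CNN1 at 1.05 (0.10 to 2.09 over arrays), PTPRC at 0.26 ± 0.37 (-0.25 without normalization within arrays, where the median of all genes was -0.38), POSTN at -0.41 ± 0.43 and S100A8 at -0.30 ± 0.33. In the tail-lengthening and cumulus lists the median of gene means was negative (-0.06 in both) while the mean was positive (0.09 and 0.10), and in the stroma list the median of gene means was positive (0.17) while camera placed the list below the other genes. With 1 array left out, the median of gene means ranged from -0.18 to 0.31 for the stroma list and from -0.17 to 0.11 for the cumulus list.

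The remaining lists did not pass. Chromatin and reprogramming regulators had a median of -0.11 ± 0.13 (46 genes, camera adjusted p = 0.386), with KAT5 at 1.71 ± 0.77 and SETDB1 at 1.67 ± 0.92 against SUZ12 at -2.15 ± 1.11 and CBX5 at -2.37 ± 2.22, of which a second probe stood at 0.69. Small GTPase and vesicle traffic genes had 0.07 ± 0.04 (137 genes, camera adjusted p = 0.858), with RAB1A at 2.48 ± 0.87 against ARF4 at -2.34 ± 0.95 and COPB2 at -1.85 ± 0.69, of which a second probe stood at 0.00. In that list SNX12 was not well above background in A- on any array. The bound from its means, 4.15-fold toward A150, was the same as the fold of its mean ratio and is no lower limit. The log2 ratio of SNX12 was 1.38 to 2.48 on single arrays and ranged from 1.08 to 3.17 over the alternatives. Ubiquitin ligases and conjugation genes had 0.02 ± 0.11 (171 genes, camera adjusted p = 0.677), with RNF10 at 1.51 ± 0.11 and UBE3B at 1.56 ± 0.42 against UBE2Q2 at -2.73 ± 1.10 and FBXL14 at -1.40 ± 0.37. By gene, 77 of them were positive and 94 negative, and the median of gene means was -0.06. Abundant non-coding and ribosomal RNA genes, here 20 microRNA and other loci, had -0.06 ± 0.27 (camera adjusted p = 0.386). Mitochondrially encoded genes had 0 measured members, and PLAT and GAPDH were not measured.

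Single named genes rest largely on 1 probe each. Of 100 named genes, 40 had further kept probes, and in 11 of them a further probe lay on the opposite side. Besides the genes given so, these were H2AZ2 (0.52), MRPL22 (0.13 and 0.29), WEE2 (0.21) and TBP (0.27). In 15 others a further probe lay on the same side with a log2 ratio over 2 times smaller, among them COA8 (1.29), H1-2 (-1.98), MRPS10 (-0.13), PSMD11 (-0.51), PSMB7 (0.88 and 0.90), EIF4G2 (0.33), CDK2 (-0.94 and -0.38) and SUZ12 (-0.80). The fraction with the lower signal was above background on 0 arrays for 4 of the 100 genes and on 1 array for 10, among them RPL38, SUZ12 and COPB2.

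**Figure D2:**
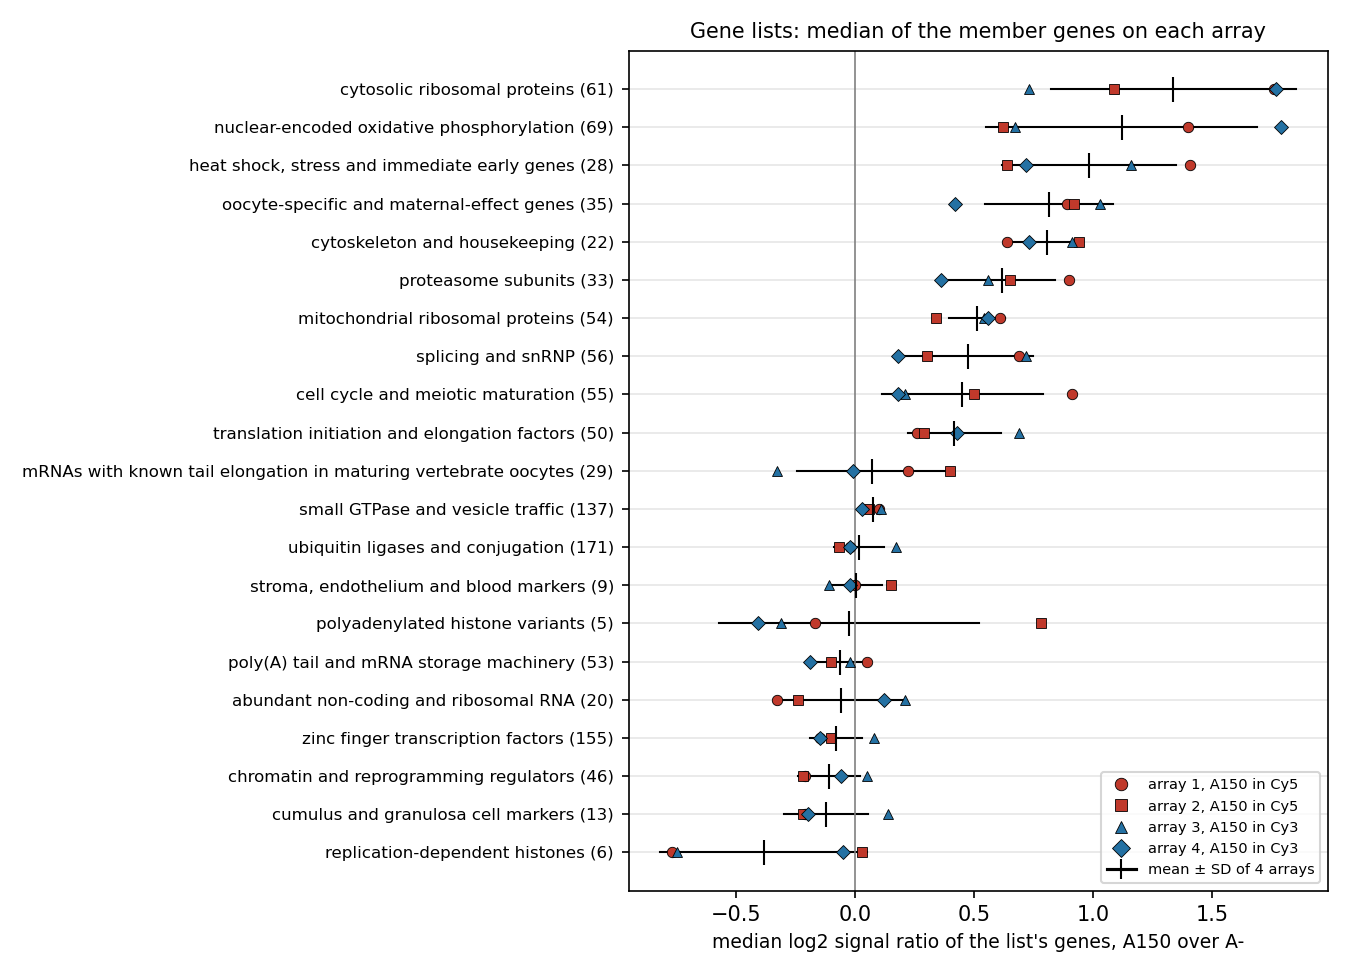
Median log2 ratio of A150 over A- of each gene list's measured genes (number in brackets) on each array, with the mean and SD of the 4 arrays in black; red symbols have A150 in Cy5 and blue symbols have A150 in Cy3. Cytosolic ribosomal proteins (1.34) and oxidative phosphorylation (1.12) lie farthest toward A150, with all 4 arrays above 0, and replication-dependent histones (-0.38) lie lowest.

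The dye entered the design as a swap of 2 arrays against 2. With the dye as a covariate, limma called 0 probes for the fraction and 0 for the dye at an adjusted p under 0.05, with 2831 and 1602 probes at an unadjusted p under 0.05. The median absolute effect over kept probes was 0.37 for the fraction and 0.33 for the dye. In that fit the translation factor list had an adjusted p of 0.0530.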

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

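The tests of dye bias, of spots near the background and of the signal of unnamed probes, and the sign patterns of the arrays for probes and genes, were chosen after the results were seen. Of 128 sets of 4 array values examined, 104 of them single genes, 3 had 1 array far from the others, and chance flags about 1 in 20. SOD2 had a log2 ratio of 0.75 on array 4 against 2.32 to 2.58 on the others. CCNB1 had 2.38 on array 2, the array with the fewest A150 probes above background, against -0.87 to -0.33 on the others. The median of the cumulus and granulosa markers was 0.14 on array 3 against -0.22 to -0.20 on the others.

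Messages for cytosolic ribosomal proteins and for oxidative phosphorylation lay toward A150 as groups. A general lean of bright probes is argued against, since the medians of gene means (1.36 and 0.90) lay above all 10000 random lists of matched mean signal (percentile 100; highest random medians 0.79 and 0.49). Dye bias is argued against, since the array medians averaged 1.43 and 1.01 with A150 in Cy5 and 1.25 and 1.23 with A150 in Cy3, with SDs over arrays of 0.52 and 0.57. Noise of dim spots is argued against, since among 956 genes above background in both fractions on all arrays the lists exceeded the median of all such genes by 0.71 ± 0.37 (26 genes) and 1.08 ± 0.58 (12 genes). Short transcript length, amplification bias and truly long tails all stay open, because transcripts were not used here.

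Probes with no gene symbol lay toward A- at bright signal. In the brightest of 10 bins of kept probes by signal the median ratio was -0.27 for unnamed and 0.31 for named probes, and among probes with an adjusted p under 0.10 the named share was 68.2% on the A150 side and 23.8% on the A- side, against 51.6% of kept probes. A difference in signal is argued against as the whole account, since within these bins named probes exceeded unnamed ones by 0.17 ± 0.04 over the 4 arrays and on each of them. Unannotated tail-less transcripts, introns and repeats may contribute, and none of these was tested.

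The 8 sign patterns of the 4 arrays, a pattern and its opposite being the same, are too few for a share under 0.05. The real pattern gave 12 probes, 0 genes, 244 probes among those above background in both fractions, and 11 gene lists. The highest of the other 7 patterns gave 0, 0, 0 and 4, and the pattern that follows the dyes gave 0 of each. In number of patterns with a count as large as the real one, these were 1 of 8, 8 of 8, 1 of 8 and 1 of 8.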

How the results depend on the processing

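Normexp against the negative-control spots and the threshold of 0.10 were chosen after the data were seen; the cause of a change was not tested unless given. The 12 probes higher in A- became 0 with no background correction, local background subtraction, median centring, no dim-probe filter, the dye covariate, the authors' log2 table, normexp against negative controls, an adjusted p of 0.01 and the unmoderated test, and ranged from 0 to 0 with 1 array left out. All 12 had a negative ratio in each of these settings, and, the change of threshold aside, the lowest adjusted p on the A- side in the settings that ended the calls was 0.0518. The count was 14 with normexp offset 0, and the same 12 were called with Aquantile between arrays and with array weights. Without normalization within arrays there were 300 probes and 89 genes higher in A150 and 355 and 49 higher in A-, and the median of all genes shifted by -0.39. With the strict filter, which tests fewer and brighter probes, there were 116 and 128 probes and 0 and 1 genes. The fit with no replicate block, which drops the pairing of fractions by array, gave 199 probes (76 higher in A150 and, rounded, 1.2e2 higher in A-) and 15 and 12 genes. At an adjusted p of 0.10 there were 151 and 151 probes and 19 and 12 genes. The authors' table gave 0 genes higher in A150 and 1 higher in A-.

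List values here are medians of gene means, not averages of array medians. Their main values were 1.36 for cytosolic ribosomal, 0.90 for oxidative phosphorylation, 0.60 for mitochondrial ribosomal, 0.72 for proteasome, 0.47 for translation, 0.68 for splicing, 0.62 for oocyte-specific, 0.50 for cell cycle, 0.67 for cytoskeleton, 1.07 for stress and -0.15 for zinc finger genes. The cytosolic ribosomal protein and oxidative phosphorylation lists passed camera's preset correlation in all 18 processing and left-out-array settings, with medians of 0.96 to 1.78 and 0.54 to 1.33. With an estimated correlation, the adjusted p was 0.127 for 10 of the 11 lists that had passed and 0.254 for cell cycle genes. With fry it was 0.0631 for proteasome, 0.0810 for cell cycle and 0.175 for zinc finger genes. With the strict filter, which leaves fewer genes and a median of 0.31 over all of them, the lists that no longer passed were mitochondrial ribosomal proteins (1.40), proteasome (0.75), translation factors (0.59), splicing (1.03), oocyte-specific (0.24), cell cycle (0.82), cytoskeleton (0.74) and stress genes (1.01), the oocyte-specific median lying below that of all genes. Zinc finger genes lost their call with median centring (-0.15), no normalization within arrays (-0.49), no dim-probe filter (-0.09), the mean of a gene's probes (-0.12) and normexp against negative controls (-0.17). Cell cycle genes lost theirs with no dim-probe filter (0.25) and no replicate block (0.50), splicing genes with no replicate block (0.68), and translation factors with the dye covariate (0.47) and the mean of a gene's probes (0.37). With 1 array left out, medians ranged from 0.49 to 0.69 for splicing, 0.34 to 0.57 for cell cycle, -0.26 to -0.07 for zinc finger, 0.43 to 0.75 for mitochondrial ribosomal, 0.60 to 0.76 for proteasome, 0.27 to 0.47 for translation, 0.65 to 0.98 for cytoskeleton, 0.62 to 1.04 for oocyte-specific, 0.96 to 1.16 for stress and -0.86 to -0.22 for replication-dependent histone genes. For named genes, 0 of which passed in the main fit, 1747 comparisons with an alternative stayed short of the threshold, which shows no stability since 0 of 100 simulated probes changed by 2 were recovered. A further 50 passed only under the alternative, and 0 reversed where the unadjusted p had been under 0.05. A slide block was not run because the files give no slide, and transcript features were not run because no transcripts were used here. Only 2030 of 19453 kept probes were above it in both fractions on all arrays.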

Other observations

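These observations were drawn after the data were seen. In genes with several kept probes, probes of 1 gene were read as separate measures of the same message, and a probe was counted on a side when its unadjusted p was under 0.05 with the same sign on all 4 arrays; none of these genes passed over all genes tested. Means and ranges are over the probes on that side only. On that reading 81 genes had at least 2 probes on the A150 side and none on the other, and 22 had at least 2 on the A- side. ATF2, a stress-responsive transcription factor, had 5 of 6 probes on the A- side with a mean ratio of -3.79 and a range of -4.27 to -2.98. The cap-binding protein gene EIF4E had 2 of 3 (-2.59), the germ cell RNA-binding protein gene DAZL 2 of 3 (-2.02), the kinase gene RIOK3 4 of 6 (-1.67) and the citrate synthase gene CS 3 of 4 (-1.41). On the A150 side, MYL6, a myosin light chain, had 9 of 11 probes (mean 2.46, range 1.58 to 3.23) and RPLP0, a ribosomal stalk protein, 9 of 12 (mean 1.89), although its brightest probe stood at 0.54 ± 1.58. The ubiquitin-like gene UBL5 had 3 of 4 (2.90), ZP3 3 of 3 (2.73), the oocyte linker histone H1-8 3 of 4 (1.71), FDPS of the mevalonate pathway 4 of 4 (1.68) and the nucleoporin gene NUP37 4 of 4 (1.43).

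In 13 genes, among them EEF1A1, HSPD1 and LHX8, probes lay on opposite sides. Shuffling gene labels within 5 bins of mean signal (1000 shuffles) gave 39.8 such genes on average and 25 to 57 in range, so opposed probes were less frequent than among unrelated genes. Probes of 1 gene correlate, so this comparison neither favours nor excludes isoforms of 1 gene with different 3' ends in different fractions, and probe positions were not used. Shuffling also gave 41.0 and 10.7 genes with at least 2 probes on the A150 or the A- side, against 83 and 22 observed.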
